A study of Mus musculus with 11 samples.

How the data were processed

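Single-cell RNA sequencing of mouse ileum was analysed from 11 libraries in 3 groups: 3 libraries of control mice given PBS, 4 of a TNBS model (trinitrobenzene sulfonic acid, a hapten used to provoke intestinal inflammation) and 4 of mice given OEA (oleoylethanolamide, a fatty acid ethanolamide) at 50 mg/kg. The labels give C57BL/6 mice and 4 mice per group. The fourth control mouse was not analysed here. The labels do not say whether the OEA mice also received TNBS, so OEA libraries were compared with both other groups. Each library was taken as 1 mouse, the unit of replication, and p-values measure the spread between these mice. The labels give no replicate numbers, so numbers within a group only name a library and pair nothing.

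Per the labels' protocols, tissue was held in a storage solution in the cold, digested enzymatically and loaded on the DNBelab C4 droplet platform, with DNBSEQ sequencing. The deposited values are whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, with no normalization, written by PISA v1.0 per the file headers. The submitters' processing notes name mm10 and Seurat; no version of Seurat is named there, and the aligner and the barcode calling are not given in the sources used here. The matrices held 157210 barcodes and 31251 genes, with 1102752169 counts in all. No barcode had under 1000 UMIs. Gene coordinates were taken from the GENCODE M21 annotation of GRCm38, the assembly called mm10.

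Cells were kept with at least 200 genes, at least 500 UMIs and at most 25% mitochondrial counts, which left 151586 barcodes. Doublets were scored per library with Scrublet in scanpy 1.11.5 at an expected rate of 6%. Its automatic thresholds called almost no cell, so a fixed score of 0.25 was used after the scores had been seen. It marked 3193 cells (2.11%), and a cluster with a high mean score was removed too, which left 148321 cells. Counts were scaled to 10000 per cell and log transformed. Clusters came from 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (Python 3.11.15, anndata 0.12.19, igraph 0.11.9, leidenalg 0.10.2). Mitochondrial, ribosomal, immunoglobulin and T cell receptor segment genes were kept out of the variable genes.

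A cluster was named after a cell type, in the sense of resembling it, only where at least 3 of that type's markers, fixed before the data were examined, were raised at least 1.5 times over the other clusters. A set of 18 genes whose counts per cell correlated with those of Gm42418, a gene that overlaps ribosomal RNA, is called rRNA-like here. A cluster with a median under 1000 counts outside those genes, or with over 60% of its counts in them and no leading marker, stayed unnamed. These limits were chosen after the data had been seen, and the share of unnamed clusters is given per group. Clusters whose leading genes held more markers of another class than of their best class (19 and 25) were compared by number.

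Raw counts were summed per library and cell class, and over all kept cells of a library, called whole ileum here. Libraries with under 20 cells of a class were left out of it, and a class was tested where each group kept at least 3 libraries, which gave 10 classes. Sums were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3, TMM scaling, filterByExpr), with all groups in 1 model and no covariate. P-values were adjusted by Benjamini and Hochberg within each class. Adjusted p-values without another tool's name come from this test. DESeq2 1.42.0 was run on the same sums as an alternative, and its missing adjusted p-values stayed missing. TMM-scaled CPM (counts scaled to a common library total) are given as mean ± SD.

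The genes named were set by a rule fixed before the data were examined. It took called genes whose libraries did not overlap between groups, at most 12 per direction and 4 per class and direction, and called members of fixed gene lists. Where fewer than 20 genes were called, the genes with the lowest unadjusted p filled the list up to 20. In addition 22 genes were always named in enterocytes and whole ileum where they were tested. Some genes that this rule or the lists would name are not reported here. Gene models with Gm or Rik symbols, numbered AC or BC clones, ribosomal, mitochondrial, haemoglobin and antigen receptor segment genes were not named. List members given below were chosen from the members that passed when adjusted over the list alone, or were named as large or known members after their values were seen.

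Of 30 gene lists fixed before the data were examined, lists with at least 5 measured genes were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01 and adjusted over all lists and classes of a comparison. The tests were repeated with an estimated correlation and with fry; for these 2 the libraries of the second group of a comparison were placed first, since the estimate depends slightly on library order. Shares of kept cells were compared by 2-sided exact permutation tests of the difference in means, where the smallest possible p is 0.0286, so a class that reaches it alone cannot pass adjustment over the 17 classes.

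Total counts per library ran from 50742545 (TNBS model 3) to 162348137 (control 3). On simulated counts drawn from the real means and library sizes, the enterocyte test recovered 17.6%, 81.8% and 90.9% of genes changed by log2 1, 2 and 3 for TNBS model against control. It recovered 23.5%, 87.9% and 97.0% for OEA against TNBS model, and 20.6%, 80.3% and 95.5% for OEA against control. Only genes above a minimum mean count were changed, and each gene was drawn independently, so recovery over all genes tested may be lower. Replicates were compared by a chi-square test of their counts, and none of the 15 pairs agreed within sampling noise.

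Alternatives changed the test, the scaling, the low-count filter, the samples in the model, the cell filters, the treatment of doublets, the clustering, a depth covariate and each left-out library in turn. Others were added after the data had been seen: removal of the rRNA-like genes, cells with at most 50% rRNA-like counts, at least 2000 UMIs, clusters made without the rRNA-like genes, and removal of TNBS model 2 with OEA 1. The planned minimum of 1000 UMIs removed no cell. For the correlation between fold changes, 10 simulated sets of unchanged groups and 6 splits of the TNBS model libraries were used.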

Results

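Ileum cells were profiled from 3 control, 4 TNBS model and 4 OEA libraries, and 148321 cells were kept. Control libraries kept 14635, 14330 and 22946 cells, TNBS model libraries 12620, 12757, 7689 and 10982, and OEA libraries 14280, 8716, 11683 and 17683. The median UMI count per kept cell ran from 3438 (OEA 1) to 6831 (OEA 2). The mean share of counts in rRNA-like genes ran from 30.7% (control 1) to 68.7% (OEA 2), and 71135 kept cells held over 50% of their counts in these genes.

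Clustering gave 35 clusters, of which 1 was removed as doublets. Enterocytes, the absorptive cells of the villus, took 33.8% ± 16.9 of control cells (SD, n = 3), 25.03% ± 13.3 of TNBS model cells (n = 4) and 27.1% ± 3.25 of OEA cells (n = 4). T and innate lymphoid cells took 21.03% ± 2.51, 16.5% ± 10.3 and 17.6% ± 7.84 in the same order, and B cells 14.3% ± 11.6, 7.55% ± 7.52 and 3.93% ± 4.91. The order of groups depends on the total. With the unnamed clusters left out of it, enterocytes took 37.9%, 36.5% and 46.2%. T and innate lymphoid cells then took 23.9%, 25.3% and 28.7%, and B cells 16.45%, 11.25% and 5.87%. Paneth cells, which secrete antimicrobial peptides at the crypt base, goblet cells, crypt stem or transit-amplifying cells (crypt cells below), plasma cells and macrophages or monocytes were large enough to test. Cluster 19, with Lef1, Dapl1, Ccr7, Satb1 and Tcf7 among its leading genes, and cluster 25, with the cycling genes Pclaf, Hmgb2, Top2a, Birc5 and Stmn1, raised 9 and 14 of 15 T cell markers, but their leading genes held more markers of another class, so they were given no name and were tested by number.

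Enterocytes were made up of Leiden clusters 0, 2, 8, 13 and 23, whose mean shares differed between groups while their libraries overlapped. Cluster 0, for one, ran from 1.92% to 33.9% in control and from 1.015% to 19.7% in OEA libraries. Shares of single clusters were not tested, and the values below are group means. They held 13.8%, 9.86%, 6.41%, 3.34% and 0.357% of control cells, 6.38%, 12.96%, 1.945%, 1.004% and 2.74% of TNBS model cells and 13.1%, 9.04%, 2.15%, 1.90% and 0.871% of OEA cells. Cluster 0 had a median of 71.8% rRNA-like counts. Clusters led by much the same genes stayed unnamed at resolution 2 and in clusters made without the rRNA-like genes. The enterocyte share thus depends on the clustering. Other classes pooled clusters too. Paneth cells were clusters 15 (1.865% of control, 3.36% of TNBS model and 1.88% of OEA cells) and 27 (0.0666%, 2.08% and 0.33%), B cells included cluster 11 (5.99%, 0.832% and 1.24%), and T and innate lymphoid cells included clusters 10 (1.77%, 3.7% and 4.62%) and 22 (3.17%, 0.885% and 0.366%). The list tests were not repeated within single clusters, so list values of a class do not separate its mix of clusters from changes within cells.

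Macrophages or monocytes made up 0.497% ± 0.326 of OEA cells (n = 4) and 1.505% ± 0.490 of control cells (n = 3), an exact permutation p of 0.0286 that did not pass adjustment (adjusted p = 0.486). With named cells alone as the total the exact p was 0.0571, and edgeR on cell counts gave p = 0.1004. Germinal centre B cells, in which antibody affinity matures, made up 0.581% ± 0.431 of OEA cells and 1.40% ± 0.268 of TNBS model cells (n = 4 each, exact permutation p = 0.0286, adjusted p = 0.486). Control libraries held 3.21% ± 2.98 germinal centre B cells (n = 3), from 0% to 5.89%, a range that spans both of those groups. For the germinal centre B cells, leaving out TNBS model 1, 2, 3 or 4 gave an exact p of 0.0571 each. Between TNBS model and control, 0 classes had p under 0.05 by the exact permutation test, and 0 by edgeR on cell counts. The 5 unnamed clusters held 11.6% ± 3.65 of control cells (n = 3), 32.5% ± 6.46 of TNBS model cells (n = 4) and 40.2% ± 13.2 of OEA cells (n = 4), with exact permutation p = 0.0286 for TNBS model against control, 0.314 for OEA against TNBS model and 0.0571 for OEA against control. The unnamed clusters are a pool whose limits were set after the data had been seen, and its make-up differed between libraries. In TNBS model libraries cluster 1 held 0.0941% to 30.3% of cells, cluster 3 0.222% to 29.7% and cluster 6 0.0549% to 17.6%. These p-values therefore do not speak for 1 population. Cells in unnamed clusters count in the total behind every share.

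**Figure D1:**
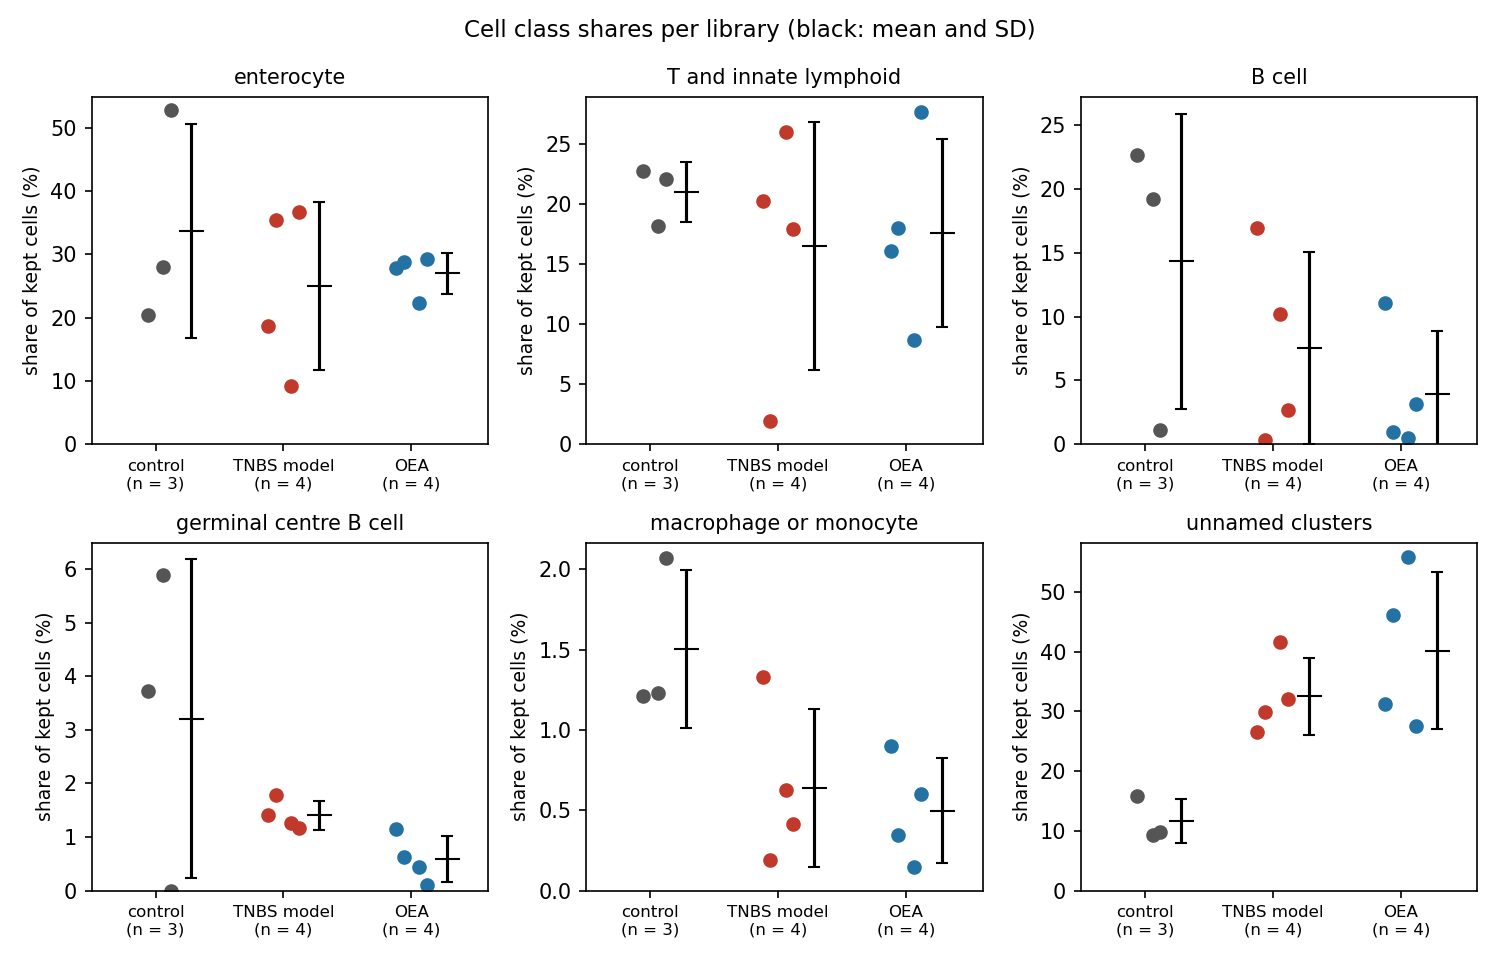
Share of kept cells (%, vertical axis) in 5 cell classes and in the unnamed clusters, 1 point per library, with the mean and SD of each group in black (bars end at the axis where the mean minus the SD lies below 0). Unnamed clusters held 9.26% to 15.8% of cells in the 3 control libraries and at least 26.6% in each other library.

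The first comparison asked what differed between TNBS model and control ileum. In crypt cells 16 of 18 measured genes of the crypt stem programme were higher in the TNBS model (median log2 0.56), among them Ascl2, a transcription factor of intestinal stem cells (log2 1.37), and Msi1, an RNA-binding protein of stem cells (1.58). The enterocyte gene Fabp6 had 357.7 to 1719 CPM in crypt sums of the TNBS model and 2643 to 4275 in those of control. Enterocyte transcripts in these sums thus differed, and the stem values need not be a change of crypt cells. Genes of the interferon-gamma response and antigen presentation lay lower in epithelial sums. Members above control were 2 of 27 in crypt cells (median log2 -0.32), 3 of 34 in enterocytes (-0.20) and 2 of 24 in goblet cells (-0.54). In enterocytes, whose mix of clusters differed on average, all 19 measured genes of carbohydrate digestion and absorption were higher (median log2 0.47). Each of these lists passed camera at its preset correlation, none passed with an estimated correlation, and no single gene passed by edgeR.

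The crypt stem list had a camera adjusted p of 1.33e-06, and adjusted p = 0.477 with an estimated correlation; 0 members passed over all genes tested and 2 passed adjusted over the list alone. The interferon-gamma list in crypt cells had a camera adjusted p of 2.94e-05 (adjusted p = 0.477 with an estimated correlation), with 0 members passing over all genes and 1 adjusted over the list alone. In goblet cells that list also had adjusted p = 0.477 with an estimated correlation, and its 1 member passing over the list alone was Ido1, which degrades tryptophan (log2 -4.69, SE 0.99, adjusted p = 0.462 over all genes). Ido1 ran from 14.97 to 266.1 CPM in control libraries and from 0.878 to 23.03 in TNBS model libraries, so the groups overlapped. B cell activation genes lay lower in the same epithelial sums, with a median log2 of -1.71 in crypt cells, -0.99 in enterocytes and -1.89 in goblet cells (adjusted p = 0.477 with an estimated correlation in each). The interferon-gamma list holds MHC class II genes, which B cells express, so its lower values need not be a change of epithelial cells. The carbohydrate list in enterocytes had a camera adjusted p of 2.58e-09 and adjusted p = 0.463 with an estimated correlation, and 0 members passed either way.

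Bile acid genes in crypt cells had a median log2 of -0.32, with 3 of 14 above control and adjusted p = 0.477 with an estimated correlation. Passing over the list alone were 4 lower members, Slc51a and Slc51b, the subunits of the basolateral bile acid exporter (log2 -1.27 for Slc51b), Fabp6, the ileal bile acid-binding protein (-1.56), and Nr1h4, the bile acid receptor FXR (-0.75); 0 passed over all genes. Enterocyte transcripts reach other classes, and Fabp6 had 508, 3553, 1489 and 1132 CPM in T and innate lymphoid sums of the TNBS model against 1812 to 3317 in control, so the crypt values need not be a change of crypt cells. In Paneth cells, whose mix of clusters differed on average, 17 of 25 antimicrobial genes were higher (median log2 0.49, adjusted p = 0.521 with an estimated correlation). Of these genes 5 passed over the list alone against 0 over all genes. They were Defa21, Defa22, Defa17, Defa26 and the ribonuclease Ang4, at log2 0.81 to 1.08; the defensins are near-identical copies whose counts may be split between them. The TNBS model 2 library had 15.8% Paneth cells against 1.66% to 2.57% in the other TNBS model libraries. Proliferation genes in enterocytes had 0 of 29 above control (median log2 -0.49, adjusted p = 0.477 with an estimated correlation), while in goblet cells 29 of 29 were above (0.53, adjusted p = 0.593).

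The genes with the lowest unadjusted p did not pass by edgeR and are given as values. Angptl4, a secreted inhibitor of lipoprotein lipase, had 14.9 ± 4.89 CPM in TNBS model enterocytes (n = 4) and 3.90 ± 0.220 in control (n = 3), a log2 of 1.94 (SE 0.29, adjusted p = 0.311 by edgeR, 1.12e-06 by DESeq2). Without TNBS model 4 its edgeR adjusted p was 0.0118. In crypt cells Upp1, uridine phosphorylase, had a log2 of -1.71 (adjusted p = 0.423), Clec2h -1.43, Gda, guanine deaminase, -1.95, Apol10a -1.91 and Zfp791 -1.74. DESeq2 called these 5, with adjusted p from 0.0152 to 0.0362. Gda was among the leading genes of enterocyte cluster 0, and Apol10a among those of enterocyte clusters 2 and 8. Fabp6 was also lower in crypt sums of the TNBS model, so the Gda and Apol10a values need not be a change of crypt cells. In T and innate lymphoid cells Duoxa2, the maturation factor of the dual oxidase of epithelium, had a log2 of -1.83 (SE 0.31, adjusted p = 0.664) and AA986860 -1.55, and in Paneth cells Defa32 had 1.11. In goblet cells Camk2b had a log2 of -3.28 (SE 0.72). Epithelial genes were among the low values of clusters 19 and 25. In cluster 19 these were Pigr, the receptor that carries antibodies across epithelium (152.9 against 404.8 CPM, log2 -1.41, adjusted p = 0.115), Dmbt1 (-1.48), Slc51a (-1.72), Prss32 (-1.93), Apob (-1.99) and the adhesion molecule Epcam (-1.34), and in cluster 25 Fabp6 (518 ± 130 against 1408 ± 308 CPM, log2 -1.46). Cluster 19 also held H2-Ab1, an MHC class II chain, at -1.38 and Cyp2c55 at 2.58, the latter with 91.1 CPM in TNBS model 1 and at most 7.90 in the other TNBS model libraries. Clusters 16 and 18, which stayed unnamed and both have Cyp2c55, a gene known from colon, among their leading genes, held 39.2% of the cells of TNBS model 1. In B cells 0 of 19 tight junction and barrier genes were above control (median log2 -0.80, adjusted p = 0.426 with an estimated correlation), and 8 passed over the list alone, among them Epcam (-1.11), Muc13 (-1.24) and Cdh1 (-1.03), against 0 over all genes. These are epithelial genes, and B cell sums hold epithelial transcripts (Fabp6 at 716 to 3598 CPM in control and TNBS model libraries).

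Over the 10 classes edgeR called 0 of 102200 gene-by-class tests (lowest adjusted p = 0.115), with 3846 at unadjusted p under 0.05. DESeq2 called 23 higher and 7 lower. Of these, 22 higher calls were in Paneth cells, where DESeq2 left the adjusted p missing for 9810 of 10326 genes. In whole ileum edgeR called 0 of 21697 genes, with 340 at unadjusted p under 0.05, and DESeq2 called 1. The count over classes was 62 without control 1, 9 without control 2, 5 without control 3, 4 without TNBS model 3 and 4 without TNBS model 4. Of 274 list-by-class tests camera called 27 higher and 86 lower, and 0 held with an estimated correlation (21 at unadjusted p under 0.05). The 1 list called by fry was the lower PPAR-alpha targets of B cells (median log2 -0.17, fry adjusted p = 6.96e-04). B cell sums hold epithelial transcripts, and their totals ran from 98307 counts (TNBS model 2) to 12215016 (control 2), so this need not be a change of B cells. Camera called the antimicrobial list lower in cluster 25, crypt cells and plasma cells although its median was above 0 there.

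**Figure D2:**
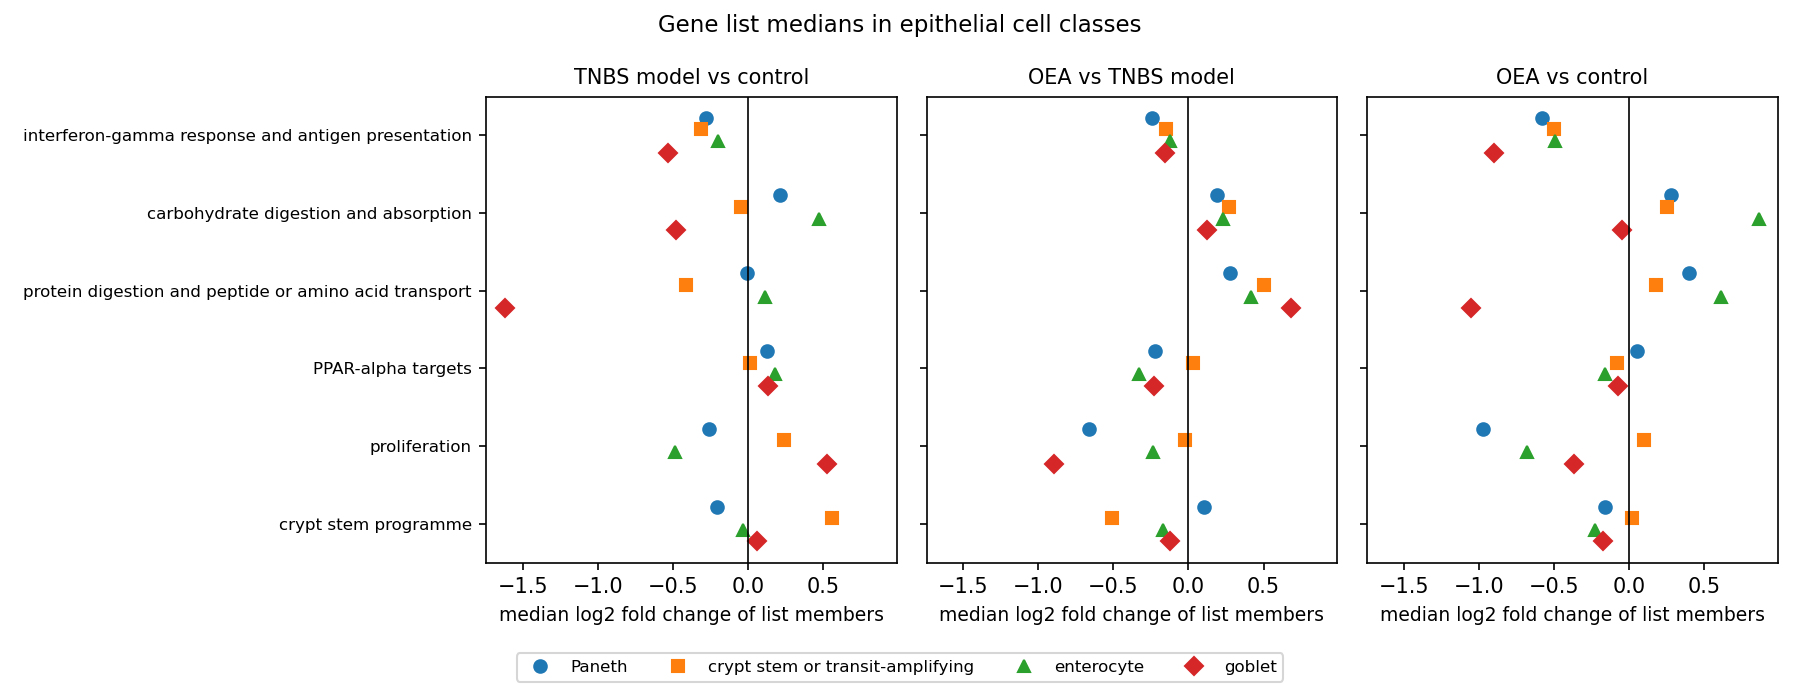
Median log2 fold change of the measured members (horizontal axis) of 6 gene lists in 4 epithelial classes, 1 panel per comparison, with symbols for the classes and a line at 0. In enterocytes the carbohydrate list had medians of 0.47, 0.23 and 0.87 in the 3 panels from left to right.

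The second comparison set OEA against TNBS model libraries. Protein digestion and peptide or amino acid transport genes lay higher in OEA in several classes, with 18 of 21 above the TNBS model in enterocytes (median log2 0.42) and 20 of 20 in crypt cells (0.50). In T and innate lymphoid sums 21 of 21 were above (0.59), but these sums hold transcripts of epithelium (Fabp6 at 508 to 4528 CPM over the libraries), so this need not be a change of those cells. In crypt cells the crypt stem programme lay lower, with 1 of 18 genes above (median log2 -0.51), including Ascl2 (-0.84) and Lgr5, a receptor that marks intestinal stem cells (-0.94). Fabp6 had 1638 to 4209 CPM in crypt sums of OEA and 357.7 to 1719 in those of the TNBS model. The protein digestion and stem values of crypt cells thus need not be a change of those cells. Goblet cells had 16 of 17 mucus and secretion genes above the TNBS model (median log2 0.51) and 2 of 29 proliferation genes (-0.89). These lists passed camera at its preset correlation, none with an estimated correlation, and no single gene passed by edgeR.

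With an estimated correlation, adjusted p = 0.722 for the protein digestion list in enterocytes, T and innate lymphoid cells and crypt cells. In crypt cells 0 members of that list passed over all genes. The crypt stem list had adjusted p = 0.722 with an estimated correlation and 0 members passing either way. The mucus list had adjusted p = 0.722 with an estimated correlation, and its 2 members passing over the list alone were Zg16, a lectin of mucus granules (log2 1.41), and Bcas1 (0.85), against 0 over all genes. The goblet proliferation list had adjusted p = 0.722 with an estimated correlation and 7 lower members passing over the list alone, such as Mcm2 (-1.94) and Tk1 (-1.78), which act in DNA synthesis, against 0 over all genes. Macrophages or monocytes went the other way, with 18 of 20 proliferation genes above (median log2 0.77, adjusted p = 0.722 with an estimated correlation) and 6 passing over the list alone, such as Ube2c (2.63) and Top2a (1.44), against 0 over all genes. In enterocytes 0 of 34 oxidative phosphorylation genes were above the TNBS model (median log2 -0.39, adjusted p = 0.759 with an estimated correlation). There cluster 0, with a median of 0.317% mitochondrial counts, held more cells in OEA on average and cluster 2, with 2.08%, fewer. Libraries of both groups overlapped in the share of either cluster. Over all enterocytes 8 of 32 PPAR-alpha targets (-0.33, adjusted p = 0.753) and 0 of 26 immediate early genes of dissociation (-0.33, adjusted p = 0.722) were above. OEA 1 and TNBS model 2 had the most Paneth transcripts in T and innate lymphoid sums, at 12.2% and 11.2% of counts.

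The genes with the lowest unadjusted p again did not pass by edgeR. Areg, amphiregulin, an epidermal growth factor receptor ligand, had 11.5 ± 6.47 CPM in cluster 25 of OEA and 47.9 ± 21.1 in that of TNBS model (n = 4 each), a log2 of -2.11 (SE 0.40, adjusted p = 0.446 by edgeR, 0.00486 by DESeq2). In macrophages or monocytes Alcam, an adhesion molecule, had a log2 of -1.77 (adjusted p = 0.576, DESeq2 0.0117), the kinase Lyn -1.18, the copper transporter Atp7a -1.94, the condensin subunit Smc2 2.31 and Xlr 2.80. In goblet cells Gmnn, geminin, had -1.99, Apex1, a DNA repair enzyme, -1.89, and Eif2ak3, the stress kinase PERK, 1.34 (adjusted p = 0.775 each). In crypt cells Slc27a2, a fatty acid transporter, had -1.27 and Slc13a2, a dicarboxylate transporter, 1.54. Slc13a2 was among the leading genes of enterocyte cluster 0, so its value need not be a change of crypt cells. Tppp in enterocytes had 1.45, C87436 and Amdhd1 in T and innate lymphoid cells 0.68 and 2.12, and Kpna6 in Paneth cells -0.98. In cluster 25 Ccnb1ip1 had 1.25, Sh2d3c 0.74 and Aebp1 -2.18, and in cluster 19 Slc7a7, an amino acid transporter, had 2.20 and Dpyd, a pyrimidine-degrading enzyme, 1.54. Angptl4 in enterocytes had a log2 of 0.93 (SE 0.25, adjusted p = 0.902).

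Over the 10 classes edgeR called 0 gene-by-class tests (lowest adjusted p = 0.446), with 3521 at unadjusted p under 0.05, and DESeq2 called 2 lower; without OEA 3 edgeR called 1. In whole ileum edgeR called 0 genes, with 535 at unadjusted p under 0.05, and DESeq2 called 0. Camera called 44 lists higher and 35 lower of 274; 0 held with an estimated correlation (16 at unadjusted p under 0.05) and fry called 0 (14 at unadjusted p under 0.05).

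The third comparison set OEA against control. Angptl4 rose in enterocytes, from 3.90 ± 0.220 CPM in control (n = 3) to 28.6 ± 6.35 in OEA (n = 4), a log2 of 2.87 (SE 0.30, adjusted p = 0.00748 by edgeR, 1.56e-18 by DESeq2), with each OEA library above each control library. It lies on chromosome 17 from 33773750 to 33781830 on the minus strand (mm10), is protein coding and is a known PPAR-alpha target. Carbohydrate digestion and absorption genes lay higher in enterocytes (18 of 19 above control, median log2 0.87), as did mucus genes in goblet cells (16 of 17, 0.74), while interferon-gamma response and antigen presentation genes lay lower in crypt cells (1 of 27 above, -0.50), enterocytes (1 of 34, -0.49), goblet cells (1 of 24, -0.90) and Paneth cells (2 of 28, -0.58). These lists passed camera at its preset correlation and none passed with an estimated correlation.

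Without control 1, 2 or 3 the adjusted p of Angptl4 was 0.0955, 0.128 and 0.0537, with clusters made without the rRNA-like genes it was 0.189, and over its 21 settings the log2 ran from 2.649 to 3.004. In raw counts the enterocyte sums of OEA held 4.91 to 7.99 times the Angptl4 CPM of T and innate lymphoid sums of the same library, and those of control 0.697 to 1.47 times. In whole ileum Angptl4 had a log2 of 1.79 (adjusted p = 0.783 by edgeR, 0.0168 by DESeq2).

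**Figure D3:**
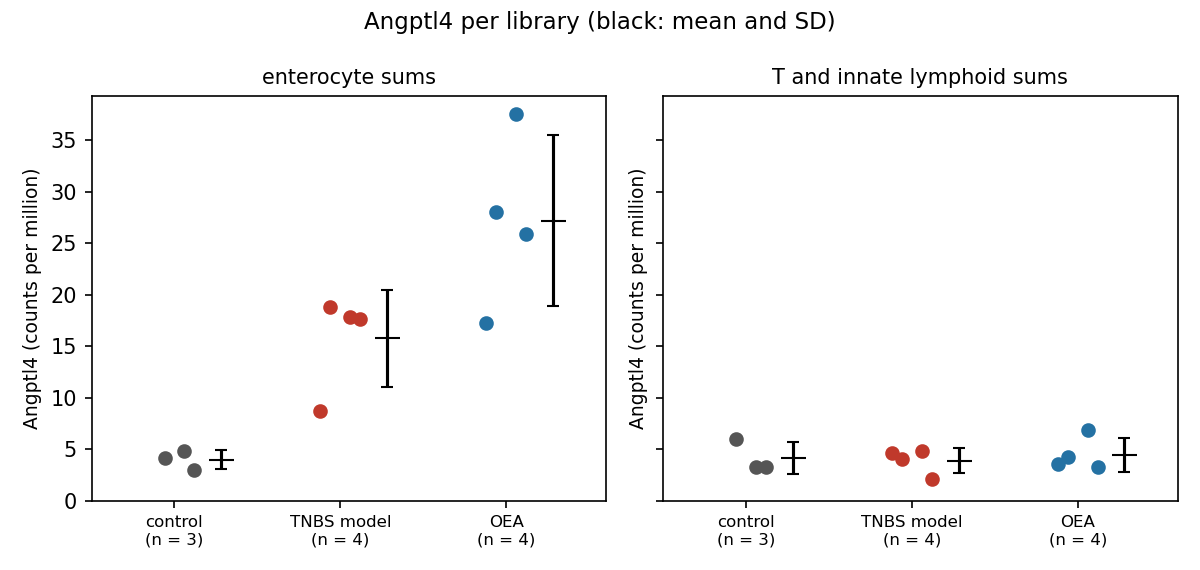
Angptl4 CPM (vertical axis, raw counts with no TMM scaling) in the enterocyte sums (left) and the T and innate lymphoid sums (right), 1 point per library, with the mean and SD of each group in black. In the T and innate lymphoid sums all libraries lie between 2.07 and 6.85.

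The carbohydrate list in enterocytes had a camera adjusted p of 5.04e-15, and adjusted p = 0.335 with an estimated correlation. Its 6 members passing over the list alone, against 0 over all genes, were sucrase-isomaltase Sis (log2 1.14, SE 0.28), the gluconeogenic enzyme Pck1 (1.01) and the sugar transporter family members Slc5a4a (2.07), Slc5a4b (1.37), Slc2a5 (1.88) and Slc2a7 (2.59). Protein digestion genes in enterocytes were higher in 18 of 21 (median log2 0.62, adjusted p = 0.432 with an estimated correlation), with Slc7a8 (0.81) and Slc6a20a (0.78) passing over the list alone and 0 over all genes. The mucus list had adjusted p = 0.335 with an estimated correlation and 6 members passing over the list alone against 0 over all genes, such as Zg16 (2.02), the trefoil peptide Tff3 (1.09) and the disulfide isomerase Agr2 (1.07); the mucin Muc2 had 1.23. In Paneth cells 17 of 25 antimicrobial genes were higher (median log2 0.57, adjusted p = 0.432 with an estimated correlation), and 8 passed over the list alone against 0 over all genes, such as Defa22 (1.17), Defa17 (1.40) and Ang4 (1.01). OEA 1 had 5.90% Paneth cells and the other OEA libraries 0.757% to 1.14%.

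The interferon-gamma list had adjusted p = 0.335 with an estimated correlation in crypt cells and 0.432 in enterocytes, goblet and Paneth cells. Members passing over the list alone were 5 in crypt cells, such as the peptide transporter Tap1 (log2 -1.18) and the GTPases Iigp1 (-4.79), Igtp (-2.42) and Irgm2 (-1.70), 4 in goblet cells, H2-Aa (-2.03), Cd74 (-1.45), H2-Eb1 (-1.42) and H2-Ab1 (-1.18) of MHC class II presentation, and 6 in Paneth cells, against 0 over all genes. B cell activation genes lay lower in the same sums, with medians of -0.29 in crypt cells, -0.91 in enterocytes, -2.17 in goblet cells and -0.95 in Paneth cells (adjusted p = 0.432 with an estimated correlation in each). B cells express MHC class II genes, so the lower values of the interferon-gamma list need not be a change of epithelial cells. The members named in crypt cells are not MHC class II genes, so this point does not cover them. Their source was not tested. T and innate lymphoid cells had a mix of clusters that differed on average, and the cycling cluster 25 was kept apart from them. In T and innate lymphoid cells 0 of 30 proliferation genes were above control (median log2 -0.73, adjusted p = 0.432 with an estimated correlation). Over the list alone 14 passed, such as Ccna2 (-1.73) and Cdk1 (-1.44), against 0 over all genes. In the same cells 2 of 24 glycolysis and hypoxia genes were above (-0.37, adjusted p = 0.432), with Hif1a (-1.10), Egln3 (-1.10), Adm and Tpi1 passing over the list alone and 0 over all genes. N-acylethanolamine metabolism and receptor genes in enterocytes had 9 of 15 above control (median log2 0.12, camera adjusted p = 0.225).

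Other genes with low unadjusted p did not pass by edgeR. In enterocytes Cyp2d26, a cytochrome P450 on chromosome 15 (82790101 to 82794294), had 14.7 ± 1.96 CPM in OEA (n = 4) and 4.44 ± 0.527 in control (n = 3), a log2 of 1.73 (SE 0.24, adjusted p = 0.084 by edgeR, 6.48e-09 by DESeq2). The scramblase Ano6 on the same chromosome (95790843 to 95974751) had a log2 of 1.44 (adjusted p = 0.123, DESeq2 3.20e-07), the inositol transporter Slc5a11 1.64 (DESeq2 2.69e-04) and Cyp2u1, a fatty acid hydroxylase, 1.35. Klf9 and H2-Aa in goblet cells had 1.27 and -2.03 (DESeq2 adjusted p = 0.0238 each). In Paneth cells the defensins Defa32, Defa31 and Defa20 had 1.30, 1.24 and 1.40. The serotonin transporter Slc6a4 in enterocytes had 0.89 (SE 0.23, adjusted p = 0.957, DESeq2 0.0492). In cluster 19 Dmbt1 had -1.90 (adjusted p = 0.159), and in cluster 25 the epithelial genes Cldn7 and Muc13 had -1.69 and -1.46. In crypt cells Cd52, a lymphocyte surface protein, had -1.78 and H2-T23 -1.02. Ifi213 in T and innate lymphoid cells had 1.03, Prg3 in plasma cells 3.86, and Sox4 and Car8 in macrophages or monocytes 1.90 and 2.79.

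Fabp1, a fatty acid-binding protein, had a log2 of 2.41 in enterocytes (SE 1.02, unadjusted p = 0.0349, adjusted p = 0.957), with 0.218 to 7.41 CPM in OEA libraries and 0.247 to 0.666 in control, and 2.59 (SE 1.003) in whole ileum. Genes of fatty acid oxidation in enterocytes lay within 2 SE of 0: Ppara 0.23 (SE 0.20), Cpt1a -0.21 (SE 0.29) and Pdk4 -0.65 (SE 0.58). So did the tight junction genes Tjp1 (0.18, SE 0.20) and Ocln (0.14, SE 0.21), the antimicrobial lectins Reg3b (-0.53, SE 0.54) and Reg3g (-0.61, SE 0.46), and Napepld (0.12, SE 0.34), Faah (0.45, SE 0.31) and Naaa (0.15, SE 0.24), which make or degrade OEA. In TNBS model against control, Slc6a4 had 0.66 (SE 0.23), Tjp1 0.05 (SE 0.20) and Reg3g 0.04 (SE 0.47) in enterocytes, and none passed. In whole ileum the cytokines Il1b and Tnf had -1.40 (SE 0.98) and -0.45 (SE 0.22) in the same comparison.

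Over the 10 classes edgeR called 1 gene-by-class test for OEA against control, with 4823 at unadjusted p under 0.05. The edgeR count was 5 without control 1 and 4 without control 3. DESeq2 called 80 higher and 5 lower. Of these, 64 higher calls were in Paneth cells, where DESeq2 left the adjusted p missing for 7613 of 10326 genes. In whole ileum edgeR called 0 genes, with 1017 at unadjusted p under 0.05, and DESeq2 called 3 higher and 2 lower. Camera called 34 lists higher and 81 lower of 274, and 0 held with an estimated correlation (29 at unadjusted p under 0.05). The 1 list called by fry was the PPAR-alpha targets of B cells (median log2 -0.20, fry adjusted p = 0.0409). B cell sums hold epithelial transcripts (Fabp6 at 950 to 5441 CPM in OEA and 2109 to 3598 in control). Their totals ran from 250299 counts (OEA 1) to 12215016 (control 2), so this need not be a change of B cells. The antimicrobial list in cluster 19 was called lower by camera although its median was above 0.

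Whether genes that differed in the TNBS model went the opposite way with OEA was examined across genes, which are not independent replicates. In whole ileum the log2 fold of OEA against TNBS model and that of TNBS model against control had a Pearson r of -0.33 and a covariance of -0.0816. Both folds use the same TNBS model libraries. Simulated unchanged groups sharing them gave a mean r of -0.467 and a covariance of -0.112, a difference in covariance of 0.0304. The simulation drew each gene independently, so this difference does not measure a departure of the real libraries from unchanged groups. With the TNBS model libraries split so that the folds share none, the mean r was 0.167 (0.101 to 0.221 over 6 splits) with a covariance of 0.0705. The 6 splits reuse the same 4 libraries, so their range is not a spread between mice. In enterocytes r was -0.407, simulated -0.481, and 0.0937 with split libraries. In goblet cells r was -0.597, simulated -0.503, and -0.107 with split libraries (-0.253 to -0.0181).

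**Figure D4:**
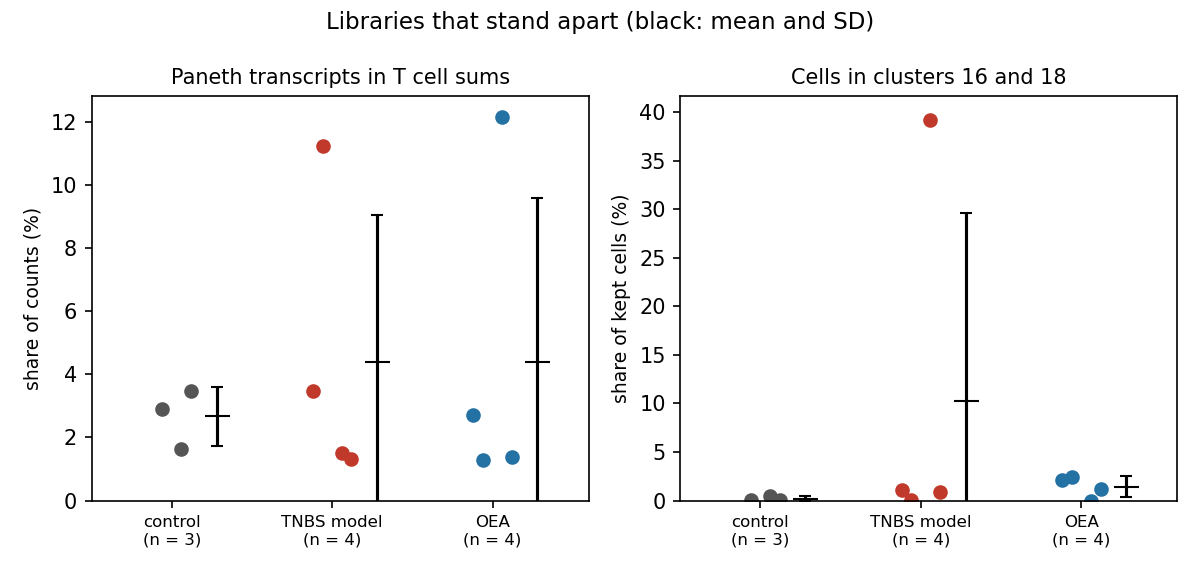
Share of counts from Paneth marker genes in T and innate lymphoid sums (left, %) and share of kept cells in clusters 16 and 18, which have Cyp2c55 among their leading genes (right, %), 1 point per library, with the mean and SD of each group in black (bars end at the axis where the mean minus the SD lies below 0). TNBS model 2 and OEA 1 stand at 11.2% and 12.2% on the left, and TNBS model 1 at 39.2% on the right.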

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

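The tests on Angptl4, on Paneth transcripts in T and innate lymphoid cells and on clusters 16 and 18 were chosen after those patterns had been seen, and the tests on the other PPAR-alpha targets and on Paneth transcripts in other classes after their own results had been seen; the counts over other splits of the libraries were planned. Among 126 groups of 4 libraries examined for a library far from the others, 10 were picked out, and chance picks out about 1 in 20 groups.

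Angptl4 was higher in enterocytes of OEA than of control libraries, by a log2 of 2.87. A different mix of enterocyte clusters is argued against as the whole cause. Within the 5 clusters the log2 had a median of 2.71 (1.44 in cluster 8 to 4.18 in cluster 13) and exceeded 2 SE in each. The mix did differ on average, with cluster 8 at 6.41% of control and 2.15% of OEA cells, though the libraries overlapped. Free RNA in the droplets would give T and innate lymphoid cells a like level, yet in 4 of 4 OEA libraries the enterocyte level was over 2 times theirs. A shift of all PPAR-alpha targets together by a like amount is argued against by the other 31 measured members, whose median log2 was -0.16, with 11 above 0. The 95% interval of that median (-0.215 to 0.00931) came from resampling these genes. The genes share the same mice and are not independent, so the interval is not a spread between mice. A small joint shift is therefore not excluded. An effect of OEA on Angptl4 itself may remain, as does an effect of TNBS if the OEA mice received it, since the TNBS model had a log2 of 1.94 over control. Counted over all classes tested, 28 of 35 splits of the OEA and control libraries gave at least 1 call. In enterocytes the real split gave 1 call, and so did the split that set OEA 1, OEA 2, OEA 4 and control 2 against the rest. No other split gave a call in enterocytes.

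Paneth marker transcripts took 11.2% of the counts in T and innate lymphoid sums of TNBS model 2 and 12.2% in those of OEA 1, against 1.29% to 3.47% in the other libraries. Free RNA from Paneth cells fits these values, as it would reach every class, and in 6 of 6 other classes both libraries lay above every other library (14.76% and 13.55% in B cells against 1.46% to 4.87%). Droplets that caught a Paneth cell with another cell were not tested. An effect of the treatment group is argued against, since only 2 of 8 treated libraries lay above every control library. No value here tells free RNA that arose in the mouse from free RNA that arose in the digestion. The same 2 libraries also had the most Paneth cells, with 15.8% in TNBS model 2 (gap to range ratio 0.936; others 1.66% to 2.57%) and 5.90% in OEA 1 (0.926; others 0.757% to 1.14%). Outside these shares lies cluster 3, unnamed for its few counts outside the rRNA-like genes and with 7 Paneth markers among its leading genes, which held 29.7% of TNBS model 2 and 55.5% of OEA 1 against 0.222% to 5.62% in the other libraries.

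Clusters 16 and 18 held 39.2% of the cells of TNBS model 1 against 0.0174% to 0.458% in control. Cluster 16 (19.3%) was led by genes that include Car1, Aqp8 and Cyp2c55, which are known from colon; of these only Cyp2c55 was among the leading genes of cluster 18 (19.9%). Colon tissue in that sample cannot be told apart from a change within the ileum, because the marker counts are few and 1 of 2 tests put TNBS model 1 highest: Best2 in goblet cells did, with 3 counts, and the posterior Hox genes were highest in TNBS model 4. Over the whole library Best2 was low in TNBS model 1, at 0.059 CPM against 0.0422 to 0.1945 in the others, and the summed colon markers Aqp4 and Fxyd4 had 215 counts there against 815 in control 1. An effect of TNBS may contribute, since 3 of 4 TNBS model libraries lay above every control library. OEA 2 (2.37%), OEA 3 (1.17%) and OEA 4 (2.10%) lay above control too, and TNBS model 2 (0.00784%) did not, so the design leaves both open.

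Other libraries far from their group are given as values, with the gap to the nearest library as a share of the group's range. TNBS model 2 had 0.917% enteroendocrine cells against 0.104% to 0.173% in the others (0.915) and 2.83% goblet cells against 0.286% to 0.610% (0.873). Cyp2c55 in cluster 19 had 91.1 CPM in TNBS model 1 against 0 to 7.90 (0.913). OEA 1 had 0.525% M cells against 0.0428% to 0.0803% (0.922) and 0.357% mesothelial cells against 0.0113% to 0.0428% (0.909). OEA 3 had 1.29% smooth muscle cells or pericytes against 0 to 0.175% (0.864). Areg in cluster 25 had 21.1 CPM in OEA 2 against 7.50 to 8.83 (0.902), and Ccnb1ip1 in cluster 25 had 20.8 CPM in OEA 1 against 17.4 to 17.8 (0.881). The unnamed clusters, outside every comparison of classes, held on average 40.2% of OEA cells against 9.26% to 15.8% in control libraries.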

How the results depend on the processing

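Of 216 alternative settings of the counts and correlations, 176 kept the value within the following limits. A count had to be equal or within 1.5 times. A correlation had to lie within its SD over the splits of the TNBS model libraries (0.0418 in whole ileum). The settings with at least 1000 UMIs removed no cell, so they could not change a value and are among the 176. Settings on rRNA-like genes, on at least 2000 UMIs and on removing TNBS model 2 with OEA 1 were chosen after seeing the data. Genes called over the classes were 0, 0 and 1 for TNBS model against control, OEA against TNBS model and OEA against control. DESeq2 called 30, 2 and 85, with most of the 30 and of the 85 in Paneth cells. Without a low-count filter, where more low genes enter, 646, 383 and 516 were called. With a median UMI covariate the first 2 became 1 and 1; the third became 3 with only the groups compared, 2 in cells with at most 50% rRNA-like counts and 0 with clusters made without the rRNA-like genes. Leaving out 1 library gave 0 to 62, 0 to 1 and 1 to 5. In whole ileum edgeR called 0 in each comparison and with each library left out (340, 535 and 1017 at unadjusted p under 0.05), while DESeq2 called 1, 0 and 5.

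Lists called by camera (113, 79 and 115) fell to 0, 0 and 0 with an estimated correlation, which was above the preset 0.01 (median 0.179, 0.183 and 0.179), and to 1, 0 and 1 with fry, which asks another question (whether the list changed at all). Leaving out 1 library gave 80 to 125, 67 to 97 and 88 to 122. The 1 class share of OEA against TNBS model became 0 within compartments, at resolution 2, with clusters made without the rRNA-like genes and by edgeR on cell counts, and 0 to 1 with a library left out. The 1 class share of OEA against control became 0 within compartments, over named cells alone and by edgeR. For comparisons with control with 1 library left out, and for all comparisons with TNBS model 2 and OEA 1 left out, the libraries are too few for the share test to reach p under 0.05, so no value is given. The correlation in whole ileum turned from -0.33 to 0.167 and in enterocytes from -0.407 to 0.0937 with split TNBS model libraries, which removes the shared libraries, and was -0.422 over genes with a mean above 50 counts. The cause of the other changes was not tested.

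Angptl4 in enterocytes of OEA against control was called in 17 of 21 settings. Over the 172 named-gene results and 3655 settings, 72 passed where the reported value had not (21 of them by DESeq2), 4 no longer passed, all of Angptl4, 92 that had not passed moved by more than 1 SE and 0 called values changed sign. Among results that were not called, the sign changed in 155 settings. Simulated genes changed by a log2 of 1 all lay above a minimum mean count. The test recovered 17.6% to 23.5% of them in enterocytes, 36.8% to 52.9% in T and innate lymphoid cells and 0% to 8.82% in whole ileum.

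Other splits of the libraries were counted for each comparison. For genes over the classes, 35, 35 and 28 of 35 splits gave at least as many calls as the real 0, 0 and 1, with up to 2664, 285 and 25 in another split. For whole ileum 35, 35 and 35 of 35 did, with up to 5, 11 and 0. For lists, 4, 14 and 3 of 35 splits gave at least as many as the real 113, 79 and 115, with up to 123, 109 and 117. Where the real count is 0 every split gives at least as many, so that count decides nothing; for the others chance is not excluded. The split with 2664 calls set TNBS model 1 and 4 with control 2 and 3 against the rest, with 2661 calls in enterocytes. It is the highest of 35 splits, and whether it reflects a structure of the samples other than the groups was not tested.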

Other observations

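The lists and their tests were fixed before the data were examined, and which of them to describe here was chosen after their results were seen. In whole ileum the extracellular matrix list lay lower in OEA than in the TNBS model, with 2 of 29 genes above (median log2 -0.68, camera adjusted p = 2.12e-06, adjusted p = 0.732 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. In T and innate lymphoid sums the same list had 1 of 17 above (median log2 -0.76, adjusted p = 0.722 with an estimated correlation). Fibroblasts made up 0.497% of TNBS model and 0.186% of OEA cells and mesothelial cells 0.346% and 0.1085%, so fewer matrix-forming cells, and less of their RNA in other classes, may give both values. Cholesterol synthesis genes in goblet cells had 23 of 24 above in OEA against TNBS model (0.46, adjusted p = 0.722 with an estimated correlation) and 22 of 24 against control (0.53, adjusted p = 0.432). Unfolded protein response genes had 21 of 24 above control in OEA goblet cells (0.39, adjusted p = 0.432 with an estimated correlation) and 21 of 25 in Paneth cells (0.22, adjusted p = 0.439).

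In macrophages or monocytes the type 2 immunity and mast cell list had 12 of 14 genes above control in the TNBS model (median log2 1.19, camera adjusted p = 3.42e-05, adjusted p = 0.477 with an estimated correlation) and 12 of 14 in OEA (1.66, adjusted p = 0.432), among them the mast cell genes Kit (1.54) and Mcpt1 (1.85) in OEA; 0 passed over all genes or adjusted over the list alone. The main clusters included none of mast cells, and at resolution 2 a cluster of 83 mast cells split off, so mast cells counted in the class may give these values. In T and innate lymphoid cells cytotoxic effector genes had 17 of 23 above control in the TNBS model (0.14, adjusted p = 0.593 with an estimated correlation) and 18 of 23 in OEA (0.34, adjusted p = 0.440). In enterocytes the same list had 2 of 20 above in the TNBS model against control (-0.70, adjusted p = 0.517 with an estimated correlation) and 18 of 20 above in OEA against TNBS model (0.47, adjusted p = 0.722). These are lymphocyte genes, so in enterocyte sums they may come from RNA of T cells. With innate lymphoid cells, T cells made up 21.03% of control, 16.5% of TNBS model and 17.6% of OEA cells. With the unnamed clusters left out of the total these shares were 23.9%, 25.3% and 28.7%, so the lower share in the TNBS model depends on that total.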
